A study of Pseudomonas aeruginosa with 4 samples.

How the data were processed

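Total RNA of *P. aeruginosa* PAO1 grown with L-Hyp or D-Hyp (5 mM each, with 10 mM L-glutamate) was hybridised to Affymetrix GeneChip arrays after cDNA synthesis, fragmentation and biotin labelling, per the labels' protocols. Each group, taken from the sample titles, has 2 arrays. The deposited values are an intensity per probe set on a linear scale, made by the authors with GCOS 1.4.0 (Affymetrix's GeneChip Operating Software), per the submitters' processing notes. The target of the scaling, the background settings and the detection calls are not given in the sources used here. The 2% trimmed means of the 5896 probe sets lay between 500.7 and 500.8 on all arrays, so the values had been scaled per array before deposit. Such scaling sets the mean signal of every array equal, and a change of the whole transcriptome cannot be seen after it.

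The table holds 5545 probe sets of PAO1 genes, 1 per locus tag, of which 5500 are in the platform table. Of the locus tags, 5504 were found in the RefSeq gene table (assembly ASM676v1), which was used only for names and for which genes are neighbours, and 1735 genes had a name. No probe positions were used. Intergenic, tRNA, rRNA, control and other-sequence probe sets were left out of the main comparison. The highest of 9 negative control probe sets, of yeast and plant sequences, read 20.5 on any array. Between 94.4% and 96.1% of gene probe sets on each array were above this value.

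Values were taken as log2 of the signal plus 43.8, the 10th percentile of all gene values, without further normalization, because the trimmed means differed by less than 5%. Fold changes are on this scale, which understates changes of dim genes. Genes were tested where their mean over all 4 arrays was above the 25th percentile of such means (a signal of 100.2), which left 4158. The difference D-Hyp minus L-Hyp was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, group as the only term), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fit had 2 residual degrees of freedom and 3.85 from the prior, and the lowest adjusted p was 0.00149. At an unadjusted p under 0.05 there were 1224 genes. Intervals are limma's at 95%. Between replicates the log2 values correlated with r = 0.972 (L-Hyp) and 0.974 (D-Hyp) across genes, and between groups with r from 0.908 to 0.952.

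The 25 gene lists, the tests, the filter and the alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 21 lists tested, and again with the correlation estimated from the data and with fry. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit, so a list can hardly pass it. Named genes are every member of the hydroxyproline gene region, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, and the 4 members with the largest difference of each other list that passed camera. The further genes named in the text (recA, lexA, prtN, pcrR, arcA, dadA, dauA, dauB, putA, gdhB, mexF, oprN, katA, fliD, PA1103 and PA3446) were chosen after their values had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

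The fit was tested on simulated data for this comparison, with 200 of 4158 genes changed and 20 runs. It recovered 95.7% of genes changed 2-fold and 99.8% of those changed 4-fold, 5.57% of its calls were false, and with no gene changed it called at most 6. A shifted list was called in 20 of 20 runs and an unshifted list in 0. The simulated genes varied independently of each other. In the data, the estimated correlations of the 6 lists that passed camera ran from -0.05 (quorum sensing) to 0.98 (type VI). The simulation therefore does not show how often correlated genes or lists are called falsely. Its noise also had the variances that limma shares across genes, which spread less between genes than those of single genes. The share of changed genes recovered can therefore be higher than in the data.

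The alternatives were 4 times the pseudocount or none, no filter or one at the median, quantile normalization, median centring, no intensity trend, the replicate number as a block, and leaving out each array in turn. In the last, the single array left in a group is assumed to vary like the other group.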

Results

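The data were 4 Affymetrix GeneChip arrays of *Pseudomonas aeruginosa* PAO1, a sequenced laboratory strain of this soil bacterium and opportunistic pathogen. All cultures grew with shaking at 37 °C in the same minimal medium with 10 mM L-glutamate, and were harvested at an optical density between 0.4 and 0.6. To this medium either L-hydroxyproline (L-Hyp, 2 arrays) or D-hydroxyproline (D-Hyp, 2 arrays) had been added at 5 mM. Hydroxyproline is a modified proline abundant in collagen, and the L and D forms in the labels differ in configuration at the carbon that carries the amino group. Every array had been scaled to nearly the same mean signal, with 2% trimmed means between 500.7 and 500.8. The median signals were 206 on both L-Hyp arrays, 217 on D-Hyp replicate 1 and 215 on D-Hyp replicate 2. The number of arrays, 2 per group, limits the precision of every value, and detection calls were not used here. The labels describe the arrays as independent experiments. The p-values set each difference between these 4 samples against variation between replicates that limma shares across genes. Cultures without hydroxyproline were not analysed here, so all differences are between the 2 forms and show no induction by either.

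The comparison asks which transcripts of PAO1 depend on the form of hydroxyproline supplied at a matched dose. With D-Hyp, 25 of 39 tested type III secretion genes and 27 of 33 tested pyocin genes were higher than with L-Hyp, and the other 14 and 6 did not pass. As lists both passed camera with the preset correlation, and both calls were lost with an estimated one (adjusted p = 0.566 with an estimated correlation for each). The type III gene exoS (PA3841), which encodes a secreted toxin, rose 6.57-fold, and arcD (PA5170), which encodes the arginine/ornithine antiporter, rose 6.01-fold (n = 2 per group, on the scale of log2 of signal plus 43.8). In the hydroxyproline gene region itself, PA1265 and PA1266 fell by 0.99 and 0.77 on the log2 scale with D-Hyp, while 13 other tested members did not pass. Transcripts of ribosomal proteins, the tricarboxylic acid cycle, ATP synthase and NADH dehydrogenase were bounded within 2-fold. By limma with Benjamini-Hochberg adjustment, 335 of 4158 tested genes (8.06%) passed an adjusted p threshold of 0.05, 214 of them higher and 121 lower with D-Hyp, a share of 63.9% higher. Centring each array on its median gave 387 genes, of which 49.1% were higher, so the balance of directions rests on the scaling. Without L-Hyp replicate 2 the count was 892, with 469 higher and 423 lower.

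PA1673, which encodes a hemerythrin-like protein, rose by a log2 difference of 2.45 (SE 0.11, limma adjusted p = 0.00149), from a signal of 304 ± 12.4 with L-Hyp to 1859 ± 79.2 with D-Hyp (SD, n = 2 each). PA2501 rose by 2.43 (SE 0.11), and PA4577, PA1746 and PA4611 rose by 2.31, 2.30 and 2.29. The log2 differences of rfaD (PA3337), encoding a heptose epimerase of lipopolysaccharide core synthesis, and PA3309, encoding a universal stress protein, were 2.26 (SE 0.18) and 2.14 (SE 0.19). The rise of exoS was 2.72 (SE 0.45, limma adjusted p = 0.0286) and that of arcD 2.59 (SE 0.51, limma adjusted p = 0.0417). The L-Hyp arrays lay far apart for exoS, with signals of 132 and 454, and its difference was 1.97 without L-Hyp replicate 1 and 3.47 without L-Hyp replicate 2. They also lay far apart for arcD, with a mean signal of 619.7 ± 501 against 3332 ± 184 with D-Hyp (SD, n = 2 each), and its difference was 3.45 and 1.73 without L-Hyp replicates 1 and 2. PA0624 of the pyocin region (2.28), popB (PA1708, 2.23) and popD (PA1709, 2.11), which encode the type III translocator proteins, completed the 12 largest rises. On L-Hyp replicate 2 the signal of PA0624, 14.2, was not above the highest negative control of that array (20.5), so its size is uncertain, with 2.91 and 1.65 without L-Hyp replicates 1 and 2. The calls of arcD with no filter on dim genes and of PA0624 with no pseudocount were lost, with limma adjusted p of 0.0561 and 0.0614.

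PA2027 had the largest fall, with a log2 difference of -2.78 (SE 0.41, limma adjusted p = 0.0204), from 1528 ± 899 with L-Hyp to 169 ± 52.5 with D-Hyp (SD, n = 2 each). The difference of PA2027 was -2.16 without L-Hyp replicate 1 and -3.40 without L-Hyp replicate 2. The neighbours PA2275 and PA2276 fell by 2.16 (SE 0.37) and 1.70 (SE 0.27), and PA2807 fell by 1.80 (SE 0.27). PA0578 fell by 1.46, and pcoA (PA2065), a copper resistance gene, fell by 1.42 (SE 0.15, limma adjusted p = 0.00779). PA0266, which encodes a gamma-aminobutyrate aminotransferase, fell by 1.17 (SE 0.13, limma adjusted p = 0.00829), and thiL (PA4051), encoding thiamine monophosphate kinase, fell by 1.15 (SE 0.12). The remaining 4 of the 12 largest falls were PA1189 (-1.35), PA4023 (-1.19), PA4292 (-1.12) and PA2047 (-1.11). Without L-Hyp replicate 1, PA2807, PA4023 and PA4292 missed the threshold by limma, with adjusted p of 0.0559, 0.0953 and 0.0585, and PA4023 also missed it with no filter (0.0589) or no pseudocount (0.0529). The exact permutation test of any single gene, 2 arrays against 2 and two-sided, cannot give a p below 0.333, so the calls rest on the variance that limma shares across genes.

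**Figure D1:**
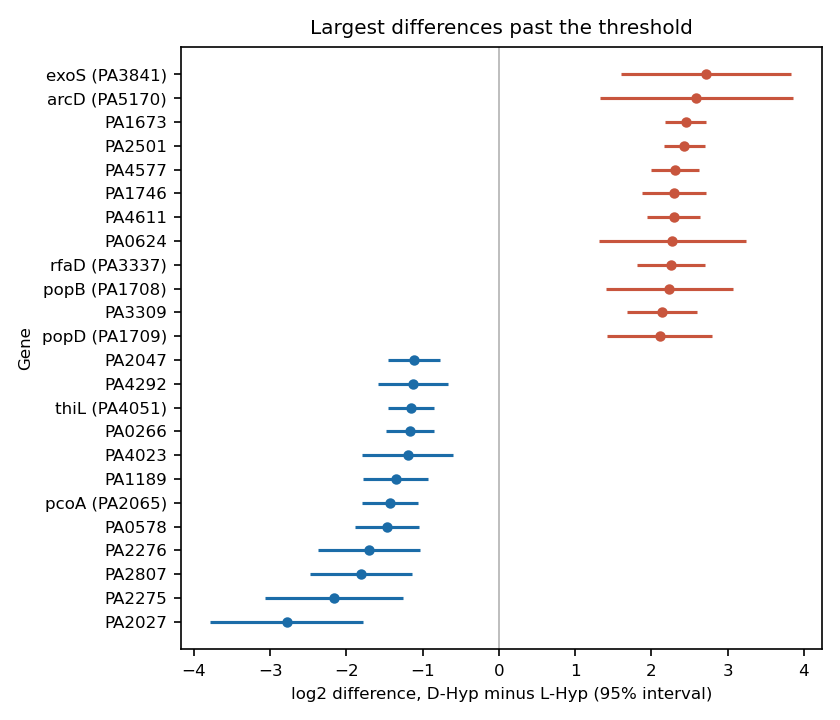
The 12 largest rises and 12 largest falls past the threshold, as log2 differences of D-Hyp minus L-Hyp (horizontal axis) with 95% intervals from limma; each point is 1 gene, red higher and blue lower with D-Hyp. The differences run from -2.78 (PA2027) to 2.72 (exoS), and the intervals of exoS and arcD are among the widest.

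The hydroxyproline gene region, PA1252 to PA1268, holds the genes for uptake and degradation of hydroxyproline. Among its 15 tested members, 0 were higher and 2 were lower with D-Hyp, and adjusted over the list alone the counts were again 0 and 2. PA1265, one of the genes of D-hydroxyproline dehydrogenase, had a signal of 283 ± 31.2 with L-Hyp and 121 ± 7.89 with D-Hyp (SD, n = 2 each), a log2 difference of -0.99 (SE 0.14, limma adjusted p = 0.0204). PA1266 of the same enzyme had signals of 2916 ± 42.1 and 1698 ± 78.2, a difference of -0.77 (SE 0.11, limma adjusted p = 0.0224). PA1267, also of this dehydrogenase, had a difference of -0.59 (95% interval -0.98 to -0.20, limma adjusted p = 0.0778) and did not pass. The 2-epimerase gene PA1268, whose enzyme interconverts the L and D forms, had a difference of -0.31 (95% interval -0.80 to 0.18). PA1253 and PA1257 had differences of -0.35 and -0.20, and PA1259 one of -0.13. For PA1254, the deaminase gene, the difference was -0.08 (95% interval -0.73 to 0.57). The remaining tested members PA1252, PA1255, PA1256, PA1258, PA1260, PA1263 and PA1264 had differences between -0.07 and 0.11. Of the 15 members, 13 had 95% intervals within 2-fold in either direction. PA1261, the regulator gene of the region, and PA1262 were too dim to be tested, with mean signals of 114 and 60.7 with L-Hyp and 78.2 and 26.4 with D-Hyp. The mean difference of the list was -0.23 and its median -0.08, and camera with the preset correlation gave an adjusted p of 0.111 (adjusted p = 0.640 with an estimated correlation). With no filter the preset correlation gave a camera adjusted p of 0.0480 (adjusted p = 0.664 with an estimated correlation). The list's median difference was -0.13 without L-Hyp replicate 1 and -0.06 without L-Hyp replicate 2. This region is also described in published work, perhaps on these samples, so the list is not independent evidence of a direction. The call of PA1266 was lost without D-Hyp replicate 1 (limma adjusted p = 0.0544) and without D-Hyp replicate 2 (0.0789). The members past the threshold were 6 lower without L-Hyp replicate 1, and 3 lower with 1 higher without L-Hyp replicate 2, where the L-Hyp group was a single array. With quantile normalization 4 members were lower, PA1267 and PA1253 being added with limma adjusted p of 0.0410 and 0.0434.

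**Figure D2:**
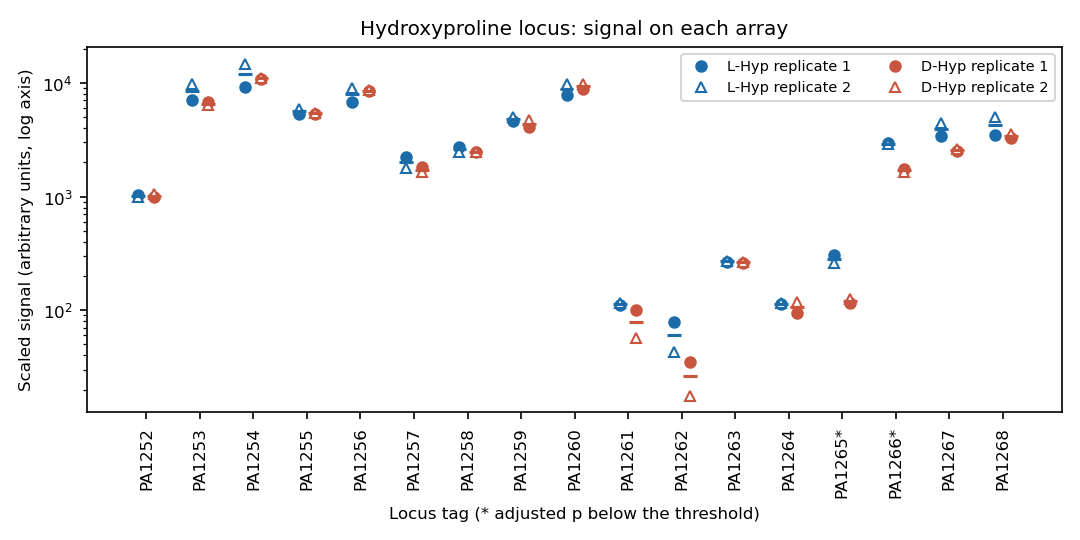
Signal of each gene from PA1252 to PA1268 (horizontal axis) on each of the 4 arrays, in the arbitrary units of the deposited table on a log axis; circles are replicate 1, triangles replicate 2, blue L-Hyp, red D-Hyp, short lines the group means, and asterisks mark genes past the threshold. PA1265 and PA1266 are the pair marked, with both D-Hyp arrays below both L-Hyp arrays.

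Type III secretion, the needle-like apparatus that injects toxins into host cells, had 25 of 39 tested genes higher and 0 lower with D-Hyp, and 14 did not pass. Adjusted over the list alone, 37 were higher. The toxin genes exoS and exoT (PA0044) rose by 2.72 and 2.04 on the log2 scale, exoT with SE 0.41 and limma adjusted p = 0.0425. The difference of exoS was 1.97 and 3.47, and that of exoT 1.36 and 2.71, without L-Hyp replicates 1 and 2. All 39 differences were positive, from 0.32 for pcrR to 2.72 for exoS, with a median of 0.93. Camera with the preset correlation gave an adjusted p of 7.91e-20 (adjusted p = 0.566 with an estimated correlation). The L-Hyp arrays differed from each other in the same genes, with a median of replicate 1 minus replicate 2 of -0.42. The call of exoT was lost with no filter (limma adjusted p = 0.0567) and without the intensity trend (0.0506).

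Pyocins, the phage-tail-like and soluble bacteriocins of this species, had 27 of 33 tested genes higher and 0 lower with D-Hyp, and all 33 were higher adjusted over the list alone. PA0622 rose 3.61-fold, from 287 ± 19.3 to 1150.0 ± 64.3 (SD, n = 2 each, limma adjusted p = 0.00253). PA0633 rose by 1.65, and PA0624 and PA0617 passed with signals on L-Hyp replicate 2 of 14.2 and 8.04, not above the highest negative control of that array (20.5). The activator gene of pyocins, prtN (PA0610), rose by 0.69 (SE 0.14, limma adjusted p = 0.0419) and lost its call in 5 of 12 alternative settings, with adjusted p up to 0.173 (without D-Hyp replicate 1). The list's median difference was 1.31, and camera with the preset correlation gave an adjusted p of 3.4e-24 (adjusted p = 0.566 with an estimated correlation). With no pseudocount the call of PA0617 was lost (limma adjusted p = 0.0718). The regulators of the DNA damage response, recA (PA3617) and lexA (PA3007), had differences of -0.21 (95% interval -0.49 to 0.07) and -0.04 (95% interval -0.32 to 0.25). Neither of these 2 passed, 0 passed when adjusted over the list alone, and their list was too short for camera.

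The type VI secretion cluster HSI-1, which delivers toxins to neighbouring bacteria, had 1 of 18 tested genes past the threshold. This was vgrG1 (PA0091), which rose 3.53-fold (log2 difference 1.82, SE 0.29, limma adjusted p = 0.0256). The differences of hcp1 (PA0085), clpV1 (PA0090) and PA0083 were 1.77, 1.66 and 1.58, with limma adjusted p of 0.0923, 0.0530 and 0.0658. Without L-Hyp replicate 1 these 3 differences were 0.93, 1.07 and 0.94, and without L-Hyp replicate 2 they were 2.61, 2.25 and 2.23. Adjusted over the list alone, 15 of 18 were higher, and all 18 differences were positive with a median of 1.11. Camera with the preset correlation gave an adjusted p of 2.85e-07 (adjusted p = 0.640 with an estimated correlation). The L-Hyp arrays were themselves apart in these genes, by a median of -1.06 for replicate 1 minus replicate 2, against 0.35 for the D-Hyp arrays. The members past the threshold numbered 18 without L-Hyp replicate 2, 3 without L-Hyp replicate 1, 7 without D-Hyp replicate 1 and 17 without D-Hyp replicate 2.

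Quorum sensing genes and their exoproducts had 3 of 16 tested members higher, 0 lower and 13 that did not pass, with 5 higher adjusted over the list alone. The hydrogen cyanide synthase genes hcnA (PA2193) and hcnB (PA2194) rose by 1.39 (SE 0.23) and 1.25 (SE 0.23), and the elastase gene lasB (PA3724) rose by 0.74 (SE 0.15, limma adjusted p = 0.0434). For hcnC (PA2195) the difference was 0.63 (limma adjusted p = 0.165). The list's camera adjusted p was 0.00870 (adjusted p = 0.566 with an estimated correlation), and it was 0.0649 with the stricter filter on dim genes. Only hcnA kept its call among these 3 without L-Hyp replicate 1, where hcnB and lasB had limma adjusted p of 0.0645 and 0.0758. Without L-Hyp replicate 2, 6 members passed. The lasB call was also lost without D-Hyp replicate 2 (limma adjusted p = 0.149) and with no filter (0.0592), where hcnB had 0.0517.

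Heat shock genes had 2 of 11 tested members higher and 0 lower, with 4 higher adjusted over the list alone. The disaggregase gene clpB (PA4542) rose by 0.77 (SE 0.12, limma adjusted p = 0.0263) and the protease gene hslV (PA5053) by 0.69 (SE 0.13, limma adjusted p = 0.0346). The chaperone genes htpG (PA1596) and grpE (PA4762) had differences of 0.67 and 0.61 (limma adjusted p of 0.0638 and 0.0799). The list's camera adjusted p was 0.0133 (adjusted p = 0.566 with an estimated correlation). Without D-Hyp replicate 1 the list's adjusted p was 0.120, and hslV then had a limma adjusted p of 0.0971, which left 1 member. With quantile normalization 4 members were higher, and without L-Hyp replicate 2, 6 were.

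Denitrification, respiration with nitrate and its reduction products, had 5 of 18 genes bright enough to be tested. The nitrite reductase gene nirS (PA0519) rose 4.07-fold, from 125 ± 12.6 to 642 ± 10.7 (SD, n = 2 each, limma adjusted p = 0.00253). The differences of nirM (PA0518), nosZ (PA3392) and narI (PA3872) were 0.84, 0.36 and 0.35, and 4 of the 5 did not pass, with 2 higher adjusted over the list alone. Camera with the preset correlation gave an adjusted p of 0.00870 (adjusted p = 0.566 with an estimated correlation). With no filter, over all 18 genes, the list's adjusted p was 0.129. Without D-Hyp replicate 1 or without L-Hyp replicate 2, 2 of the 5 passed, as they did with 4 times the pseudocount and with the replicate block.

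Of the 21 lists with at least 5 tested members, these 6 passed camera with the preset correlation and 0 passed with an estimated one. Among the 6, the estimates ran from -0.05 (quorum sensing) and 0.02 (denitrification) to 0.98 (type VI). Where the estimate was close to the preset 0.01, correlation between genes does not account for the loss. The second test rests on 2 residual degrees of freedom, so its 0 does not show that correlation explains all 6 calls. Where the estimate was far above the preset, as for type VI (0.98), type III (0.55) and pyocins (0.27), the preset understates the correlation. The p with the preset is then too small, most of all for type VI, whose genes varied almost as 1. By fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, 2 of the 21 passed, quorum sensing (adjusted p = 0.0130) and pyocins (adjusted p = 0.0466). Both fry calls were lost with the replicate block (0.309 each), without D-Hyp replicate 1 (0.652 each), without D-Hyp replicate 2 (0.617 each) and without L-Hyp replicate 1 (0.0772 and 0.0569). That of quorum sensing was also lost with the stricter filter (0.0784) and that of pyocins with no filter (0.0567).

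**Figure D3:**
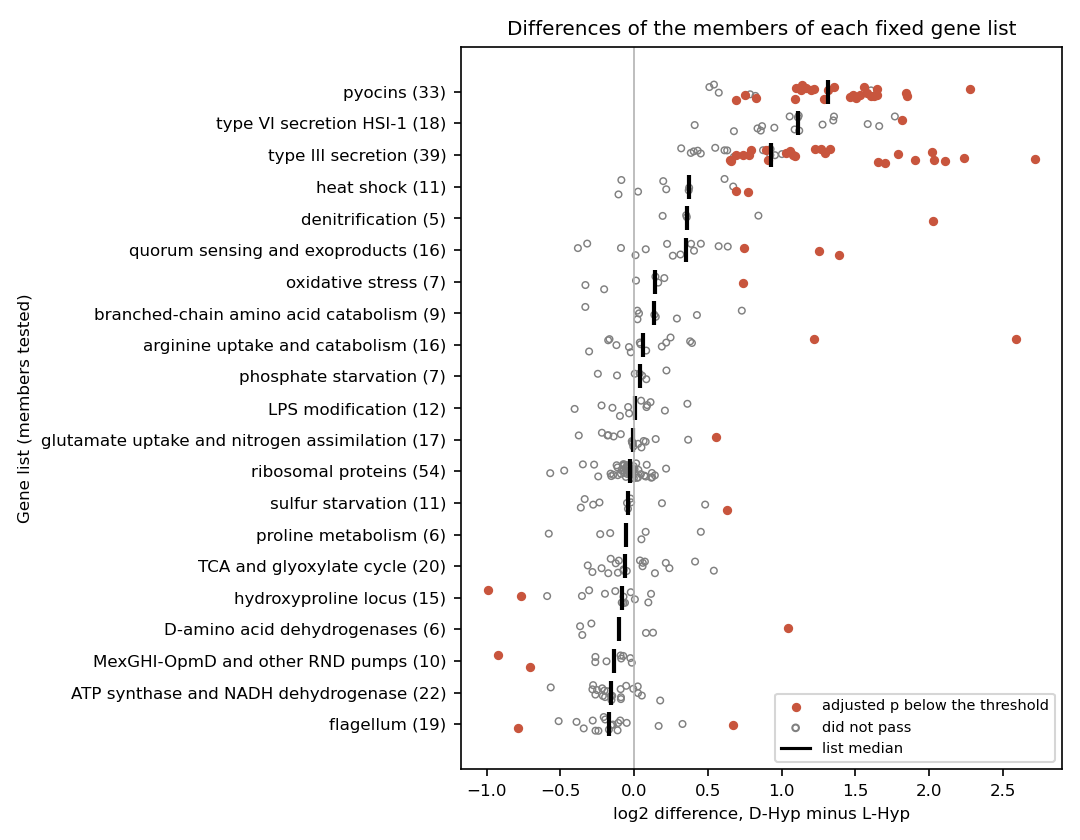
Log2 differences of D-Hyp minus L-Hyp (horizontal axis) of every tested member of the 21 gene lists with at least 5 tested members (vertical axis, members in brackets); filled points passed the threshold over all genes, open points did not, and black bars are list medians. All members of the pyocin, type VI and type III lists lie above 0, with medians of 1.31, 1.11 and 0.93.

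Genes of amino acid metabolism differed in a few members. In the arginine list arcD and arcA (PA5171), of the arginine deiminase pathway, were higher among 16 tested, arcA by 1.22 (SE 0.15, limma adjusted p = 0.0117), with 2 higher adjusted over the list alone. In the D-amino acid dehydrogenase list dadA (PA5304), whose enzyme oxidises D-alanine, rose 2.06-fold (SE 0.12 on the log2 scale, limma adjusted p = 0.0105) and was the only one of 6 past the threshold, with 1 adjusted over the list alone. The D-arginine genes dauA (PA3863) and dauB (PA3862) had differences of -0.37 and -0.35. Of 6 proline genes 0 passed, and 1 was higher and 1 lower adjusted over the list alone. The proline dehydrogenase gene putA (PA0782) had a difference of 0.08 (95% interval -0.27 to 0.42), and all 6 were bounded within 2-fold. In the glutamate and nitrogen assimilation list gdhB (PA3068), a glutamate dehydrogenase gene, rose by 0.55 as 1 of 17, 0 passed adjusted over the list alone, and all 17 were bounded within 2-fold. The gdhB call was lost in 7 of 12 alternative settings, with limma adjusted p up to 0.161 (without D-Hyp replicate 1). Of 9 genes of branched-chain amino acid catabolism 0 passed, also when adjusted over the list alone. In the glutamate list 4 genes were higher and 1 lower without L-Hyp replicate 2, where also 2 branched-chain genes were higher and 1 proline gene was lower. Camera with the preset correlation gave adjusted p of 0.237, 0.997, 0.901, 0.997 and 0.329 for these 5 lists in turn.

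All 54 ribosomal protein genes, all 20 tested genes of the tricarboxylic acid and glyoxylate cycles and all 22 genes of ATP synthase and NADH dehydrogenase had 95% intervals within 2-fold, and 0 of each list passed, over all genes or adjusted over the list alone. Their camera adjusted p were 0.822, 0.997 and 0.115, and their median differences -0.03, -0.06 and -0.16. The ribosomal protein genes differed between the L-Hyp arrays by a median of -0.51 for replicate 1 minus replicate 2. Without L-Hyp replicate 1, 4 ribosomal protein genes and 1 tricarboxylic acid gene were lower. Without L-Hyp replicate 2, 11 ribosomal protein genes, 3 of the tricarboxylic acid list and 1 of the ATP synthase and NADH dehydrogenase list were higher, and 1 ribosomal and 1 of the last list were lower. The sign of 2 of these medians turned with the L-Hyp array left out. Without L-Hyp replicate 1 the ribosomal median was -0.28 (camera adjusted p = 2.1e-12) and the tricarboxylic acid median -0.21 (adjusted p = 0.0119), both calls lost (adjusted p = 0.563 with an estimated correlation for each). Without L-Hyp replicate 2 they were 0.22 (adjusted p = 7.86e-06) and 0.17 (adjusted p = 0.0398), both calls lost again (adjusted p = 0.635 with an estimated correlation for each). The ATP synthase and NADH dehydrogenase list passed without L-Hyp replicate 1 (adjusted p = 0.00245), but not with an estimated correlation (adjusted p = 0.563 with an estimated correlation).

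Among the remaining lists, the efflux genes mexF (PA2494) and oprN (PA2495), parts of the MexEF-OprN pump, fell by 0.92 (SE 0.14) and 0.71 (SE 0.14), 2 of 10 tested pump genes and 2 adjusted over the list alone. The catalase gene katA (PA4236) rose by 0.74 (SE 0.15) as 1 of 7 oxidative stress genes, with 1 adjusted over the list alone. In the flagellum list fliD (PA1094), the filament cap gene, was higher by 0.67 and PA1103 was lower, with a difference of -0.79, among 19, and 1 in each direction passed adjusted over the list alone. Without L-Hyp replicate 2 the flagellum list had 2 higher and 4 lower members and passed camera (adjusted p = 0.0243), but not with an estimated correlation (adjusted p = 0.635 with an estimated correlation). PA3446 rose by 0.63 as 1 of 11 sulfur starvation genes, with 1 adjusted over the list alone. Of these genes, katA, fliD and PA3446 each lost the call in 5 of 12 alternative settings, with limma adjusted p up to 0.0682 (katA, without D-Hyp replicate 1), 0.149 (fliD, without D-Hyp replicate 2) and 0.167 (PA3446, without D-Hyp replicate 2). The oprN call was lost in 4 settings, with limma adjusted p up to 0.0964 (without D-Hyp replicate 1). Of 7 phosphate starvation genes and 12 lipopolysaccharide modification genes 0 passed, also when adjusted over the list alone, and all were bounded within 2-fold. A lipopolysaccharide modification gene was lower without L-Hyp replicate 2 (1 of 12), and without D-Hyp replicate 1, 2 sulfur starvation genes were higher. The camera adjusted p of these 6 lists were 0.107, 0.901, 0.115, 0.997, 0.997 and 0.997. The siderophore and phenazine genes were mostly too dim, with 2 of 17 pyoverdine genes, 0 of 9 pyochelin genes and 3 of 16 phenazine genes tested, and 0 passed in any of these lists, over all genes or adjusted over the list alone. Of the phenazine genes, 9 have probe sets of their own, and values of genes with near-identical copies are uncertain because their probe sets can bind both copies.

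Over all tested genes, 3580 (86.1%) had a 95% interval of the difference within 2-fold in either direction. The median half-width of the interval was 0.36 on the log2 scale. Both arrays of 1 form lay above both of the other for 2575 genes (61.9%), where chance gives 33.3% on average. Of these, 184 were at least 2-fold apart, 165 higher and 19 lower with D-Hyp. Genes vary together between arrays, so the share in a single split can lie far from 33.3% by chance. Differences of genes at adjacent locus tags correlated with r = 0.51 over 3479 pairs, and the highest absolute r in 1000 shuffles of gene order was 0.0473 (permutation p = 0.000999, the smallest the shuffles can give). This correlation is across genes, which are not independent replicates, and the difference between replicates gave r = 0.46 for the L-Hyp arrays and 0.48 for the D-Hyp arrays.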

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

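The tests of these probe sets were chosen after the results had been seen. The array also carries probe sets outside the genes compared, and some gave a signal above the highest negative control (20.5) on all 4 arrays: 130 of 199 intergenic, 17 of 18 tRNA, 3 of 3 rRNA and 19 of 117 other-sequence probe sets.

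Tested by limma with Benjamini-Hochberg adjustment over these probe sets alone, 6 of 15 tRNA probe sets passed. With D-Hyp the tRNA-Phe and tRNA-Arg probe sets rose by 0.76 and 0.63 on the log2 scale. The tRNA-Gly probe set had a difference of -0.99, from 3701 ± 146 with L-Hyp to 1846 ± 123 with D-Hyp (SD, n = 2 each, limma adjusted p = 0.0170). Differences for tRNA-Gln, tRNA-His and tRNA-Val were -0.73, -0.71 and -0.53. These probe sets can bind several tRNA gene copies or tRNAs of similar sequence. Of 58 tested intergenic probe sets 4 passed, 2 higher and 2 lower with D-Hyp.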

How the results depend on the processing

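None of the settings in this part was chosen after the results had been seen. The count of differing genes was 344 with 4 times the pseudocount, 307 with none, 224 with no filter, 318 with the filter at the median, 326 with quantile normalization, 387 with median centring and 268 without the intensity trend. All 335 genes kept their sign under each of these settings and with each array left out, apart from those that the filter at the median left untested (283 of 283 tested kept theirs). For a gene whose arrays do not overlap between groups, leaving out an array or changing the pseudocount, filter or trend cannot change the sign. For such genes the kept sign therefore tests only the scaling. The median of all genes was -0.02, -0.05 and -0.08 on the log2 scale as deposited, with quantile normalization and with median centring.

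The genes at least 2-fold apart without overlap numbered 96 with 4 times the pseudocount, which shrinks differences of dim genes by construction. Genes bounded within 2-fold numbered 2333 with the filter at the median, where fewer genes are tested. The mean of the hydroxyproline gene region was -0.26 with no filter, which adds PA1261 and PA1262. Its camera adjusted p of 0.0480 was then under the threshold, but not with an estimated correlation (adjusted p = 0.664). With an estimated correlation 0 lists passed.

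Without D-Hyp replicate 1, 254 genes passed, sharing 201 with the 335. Leaving out each array in turn gave 237 genes without L-Hyp replicate 1 (190 of the 335 shared), 350 without D-Hyp replicate 2 (219 shared) and 892 without L-Hyp replicate 2 (327 shared), with 152 to 261 genes at least 2-fold apart, 3226 to 3698 bounded, 5 to 10 lists and a neighbour correlation of 0.46 to 0.54. The hydroxyproline gene region's mean was -0.31 to -0.15 with an array left out. Why these results moved was not tested.

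With the replicate number as a block, 280 genes passed (lasB did not, limma adjusted p = 0.0521) and 242 were shared with the fit without it. Deviations of same-numbered arrays from their group means correlated with r = -0.05 across genes, so no pattern of deviations shared by same-numbered arrays was seen. A shift of equal size in all genes would not appear in this r. The labels do not say whether same-numbered arrays share a day or inoculum, and this r cannot tell. Dim signals limit the region's regulator gene and most siderophore and denitrification genes.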

Other observations

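The low-oxygen, zinc, ethanol and bright probe set groups, the genes named and the tests of explanations in this part were chosen after the results had been seen, while the limma fit, the alternative settings and the denitrification list were fixed beforehand. With D-Hyp genes of the aa3-type cytochrome oxidase rose, with coIII (PA0108) among them: coxB (PA0105) by 1.15 on the log2 scale (SE 0.15), coxA (PA0106) by 1.02 (SE 0.12), PA0107 by 0.84 (SE 0.12), each with n = 2 per group. The acetate kinase gene ackA (PA0836) rose by 1.48 (SE 0.13). These genes and coIII kept their calls in all 12 alternative settings.

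Beside PA0266, the succinate semialdehyde dehydrogenase gene gabD (PA0265) fell by 0.81 with D-Hyp (SE 0.14) and the polyamine gene spuB (PA0298) by 0.78 (SE 0.14), with limma adjusted p of 0.0306 and 0.0335. The gabD call was lost without D-Hyp replicate 2 (limma adjusted p = 0.0832) and without L-Hyp replicate 1 (0.0591), and spuB kept its call in all 12 settings.

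A group of 22 genes known to respond to low oxygen through the regulators Anr or Dnr was higher with D-Hyp, 21 of them past the threshold, with a median of 1.72. The group was chosen after the results had been seen, so this count and median are no test of Anr and Dnr genes as a set. It includes ccoO2 (PA1556, 2.10), ccoN2 (PA1557, 1.81), hemN (PA1546, 1.74) and oprG (PA4067, 1.45), besides PA1673, PA1746, PA3309 and rfaD. The median was 1.66 or higher under quantile normalization and median centring and 1.70 or higher with each array left out. The rise of this group was thus kept under these scalings and with any array left out. Genes chosen after their differences had been seen tend to hold in such checks. The medians therefore cannot decide whether scaling or a single deviating array contributed, here or for other genes. Less oxygen in the D-Hyp cultures at harvest may account for the rise of the group and stays open. The denitrification list fixed beforehand was higher with the preset correlation (camera p = 0.00207) but had camera p = 0.0937 with an estimated correlation. The estimate, 0.02, was close to the preset 0.01, so the second p reflects the 2 residual degrees of freedom and cannot decide. Besides, 13 of the 18 genes of that list were too dim. An effect of D-Hyp itself on these genes also stays open, as culture conditions other than the medium were not tested.

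A group of 29 tested genes of zinc limitation was high on D-Hyp replicate 1, and 1 of them, np20 (PA5499), passed the threshold between the groups (29 higher without D-Hyp replicate 2, 3 higher and 1 lower without D-Hyp replicate 1, 0 with either L-Hyp array left out). PA0781 had a signal of 8704 on that array and 370 on D-Hyp replicate 2, against 143 and 194 with L-Hyp, and of the genes at least 4-fold apart between the D-Hyp arrays, 23 of 23 belonged to this group. D-Hyp as the whole cause is argued against, since the median difference from the L-Hyp mean was 3.19 for replicate 1 and 0.31 for replicate 2. Over all tested genes the SD of the difference was 0.325 between the D-Hyp arrays and 0.347 between the L-Hyp arrays. A disturbance of D-Hyp replicate 1 across genes at large was therefore not seen. A faulty array or RNA sample stays open, since the only SD to compare with is that of a single pair of L-Hyp arrays. Low zinc in that culture could also account for the group and was not tested.

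Among the 50 brightest probe sets, L-Hyp replicate 2 exceeded replicate 1 by a median of 0.56 for the 32 ribosomal protein genes and 0.53 for the 18 others, while the median over all tested genes was -0.01. More ribosomal transcripts in replicate 2 as the whole cause is argued against, since the ribosomal protein genes exceeded the others by only 0.0307, although the 16S and 23S rRNA probe sets, left out of the 50, shifted by more (0.78 and 0.85; 5S by 0.21). An array-specific scaling of signals near the top of the range could account for the shift of 0.53 in the 18 others and stays open, since 8 of them belong to the tricarboxylic acid, ATP synthase and NADH dehydrogenase or heat shock lists and 0 of 5 spike-in probe sets were as bright. The D-Hyp arrays differed by 0.03 in the same probe sets. No biological explanation was tested beyond the ribosomal one.

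The ethanol oxidation genes differed between the L-Hyp arrays: exaA (PA1982) had a signal of 1125 on replicate 1 and 21 on replicate 2, and of 8 tested genes of this group 0 passed between the forms (8 lower without L-Hyp replicate 2, 1 higher without L-Hyp replicate 1, 1 lower without D-Hyp replicate 2), with a median difference of -0.73 that was -1.64 without L-Hyp replicate 2 and 0.23 without L-Hyp replicate 1. The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 335 genes, as the 1 split with so many, and the highest other gave 0. Each other split mixes the forms within its groups, so a difference between them adds to the variation within groups. Few calls are then likely whatever the cause of that difference, and the 0 says little.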
